A study of Homo sapiens with 8 samples.

How the data were processed

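RNA of 8 cultures was labelled with 1 dye and hybridised to Agilent human arrays with 62976 spots, of which 58717 carry 42405 distinct gene probes. The labels give 100 ng of RNA per labelling, infection at 25 moi for p53, p63g and p73b with RNA taken 24 h later, and for HCT116 an siRNA transfection, adriamycin at 0.5 ug/ml 4 h afterwards, a further siRNA transfection 24 h after the drug and RNA 24 h after that. They give no moi for LacZ, so it is unknown whether the control virus had the same dose. Each of the 8 groups holds 1 array, and every column of the value table belongs to a sample (0 without one). Per the file headers, the scanner files hold the intensity of each spot, which Agilent Feature Extraction (version 10.7 per the labels) background-subtracted and detrended within the array without scaling between arrays. The deposited value table holds log2 values, per the labels made with Feature Extraction and limma, whose roles and limma's version they do not state. The scale was found by comparison: the H1299 columns follow log2 of the median spot signal with the background left in, and the 4 columns of each line have nearly the same quantiles, as quantile normalization gives. Column medians are 6.53 (LacZ), 6.47 (p53), 6.48 (p63g), 6.48 (p73b), 6.41 (siControl), 6.42 (siControl with adriamycin), 6.43 (siAKR1B10) and 6.43 (siAKR1B10 with adriamycin).

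The plan, written before the data were examined, was to use the scanner files for both lines. For HCT116 this was changed after the files were compared, since the scanner files under the HCT116 labels do not hold the measurements of the value table's HCT116 columns (Pearson's r 0.871 to 0.889 with the file of the same label). The labels do not state which of these sources is the intended one, but the level of AKR1B10 differs between them. In the scanner files its scaled log2 signal was higher with siAKR1B10 than with siControl. It was −1.78 against −2.86 without adriamycin and −0.80 against −2.24 with it. In the value table it was lower with siAKR1B10, at −3.04 against −1.275 and 0.98 against 3.56. The silencing that the labels name is thus seen in the value table alone. HCT116 values were therefore taken from the value table and H1299 values from the scanner files, and results from the scanner files are given as an alternative. It stays unknown which slide and scan the HCT116 columns of the table come from, so no slide term could be used for them, and no matching scanner file was at hand to show how their values were made. The 4 H1299 arrays share 1 slide and 1 scan.

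In H1299 the processed signal of each probe (repeated spots averaged, outlier spots dropped) was put on a log2 scale and the array's 75th percentile was subtracted. A probe counted as above background where the scanner software marked its spots, or most of them, well above background. In the value table, which carries no such mark, a probe counted as above background at or above a detection level set from the dim mode of the values and the spread below it, calibrated on the H1299 columns, where 96.5% to 98.2% of probes got the same call as in the scanner files. In HCT116 this level was log2 6.87, a signal of 116.5, and the dim mode lay at signals of 50.1 to 55.8, against 27.1 to 29.6 in the H1299 columns. HCT116 values were the table's log2 values minus each column's 75th percentile. Because background remains in them, their folds are compressed for dim genes.

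Gene names come from the files, updated through RefSeq accessions against an annotation of GRCh38.p14, used for names only. Of the probes 24823 matched, 3778 symbols changed and 17582 kept the file's name. A gene was represented by its probe with the highest mean signal in the line among probes above background on at least 1 array. It entered a comparison when above background on at least 1 of the pair, with the lowest above-background signal in place of the dimmer value where needed. Differences were counted at an absolute log2 of 1 or more. With 1 array per group no test could be made for a pair. For HCT116 a secondary additive fit of adriamycin and siRNA used limma 3.58.1 in R 4.3.3 over 16700 genes, with 1 residual degree of freedom, which takes any interaction as noise, and Benjamini-Hochberg adjusted p under 0.05. Its prior had 3.20 degrees of freedom and an SD of 0.109. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

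The rule for named genes was TP63, TP73, AKR1B10 and members of the gene lists, and otherwise genes with a symbol whose brighter array lay at or above the 25th percentile of above-background signals. These were the 10 highest and 10 lowest for each virus, the 5 highest and 5 lowest for all 3 viruses, for each direct difference and for the difference of adriamycin differences, and the 10 highest and 10 lowest by the smaller of both changes for adriamycin and for siAKR1B10. AKR1B1 is a member of the retinoid list. AKR1B15, AFP and ALB, and the 20 liver markers, were chosen after values were seen. Some genes that the rule names are left out of the text and of the lists of highest and lowest genes there.

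There were 23 gene lists from textbook knowledge, written before the data were examined. They cover p53 targets in the cell cycle and feedback, apoptosis and DNA repair, p63-type epithelial genes, motile cilia genes linked to p73, G2/M, G1/S and replication, NRF2-type redox genes, retinoid metabolism, lipid and sterol synthesis, interferon, NF-kB cytokines, the endoplasmic reticulum and integrated stress response, heat shock, immediate-early genes, hypoxia and glycolysis, housekeeping, ribosomal proteins, genes typical of HCT116 and of H1299, and fibroblast, leukocyte and endothelial markers. Each list's median log2 difference was placed among 10000 random lists of the same size, matched in 20 bins of mean expression, and called outside their range at or beyond the 97.5 or 2.5 percentile. This describes these arrays and is no test of the conditions. Lists with fewer than 3 genes measured were left out.

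Overlaps are given with the number expected of independent lists. Where both comparisons share the LacZ array, 20 sets of arrays with no difference between groups were simulated, with the spread of repeated spots and with a wider SD of 0.154 per array. The wider SD was taken from the siAKR1B10 differences in HCT116 and does not measure the spread between H1299 cultures.

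The additive fit was tested on simulated data of 16700 genes, and its recovery depended on the spread assumed. The spread in the simulation as first set up was each gene's own residual, and with 200 changed genes it recovered 0% at log2 1, 2 and 3, while with 2189 changed genes it recovered 71.5%, 86.9% and 92.3%. The simulation was then changed, after that outcome was seen, to spreads drawn from the prior fitted on the real columns. It then recovered 58.8% at log2 1 and 100% at 2 and 3 with 200 changed genes (12 false of 184 calls), and 93.8%, 99.6% and 100% with 2189 (109 false of 2251). The siRNA term, simulated without effect, had 0 calls each time. The fit itself was not changed. On the same data the count by size, with spreads from the prior, found 47.1% (200 changed) and 50.8% (2189 changed) of genes at log2 1 and passed 116 and 105 unchanged genes. With each gene's own residual as the spread it passed 250 and 232.

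The alternatives set before the data were examined were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, scaling by the median, the median of a gene's probes, a filter on both arrays, no filter, measured values in place of bounds, and the value table for H1299. Normexp could not be run for HCT116, whose table holds no raw signal, and the slide as a block was not run. The scanner files under the HCT116 labels, the main source in the plan, became an alternative. Subtraction of the background level from the HCT116 columns, and removal of probes at least 8-fold brighter on the LacZ array than on each other H1299 array, were added after the data were seen, as was the epithelial list without TP63, which the p63g virus carries.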

Results

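Transcript levels were measured on 8 one-colour microarrays, each hybridised with RNA of 1 culture. H1299 is a lung carcinoma line, and 4 of the arrays hold H1299 cells infected with adenovirus carrying LacZ, p53, p63g or p73b. LacZ encodes a bacterial enzyme and served as the control insert, while p63g and p73b stand for the gamma isoform of p63 and the beta isoform of p73, members of the same family. HCT116 is a colon carcinoma line. The other 4 arrays carry HCT116 labels: cells received a control siRNA (siControl) or an siRNA against AKR1B10, with or without adriamycin, a DNA-damaging drug also known as doxorubicin. AKR1B10 encodes an aldo-keto reductase that reduces aldehydes and retinal. Each group held 1 array, so there is no replicate check on any value; genes were counted by the size of their difference, and a gene counted when it was at least 2-fold higher or lower.

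On the H1299 arrays 67.2% (LacZ), 69.1% (p53), 64.8% (p63g) and 70.7% (p73b) of 42405 probes were above background, and no spot was saturated. The spread between repeated spots of a probe, as the median SD of log2 signal, was 0.056 to 0.064 on these arrays. For HCT116 the values come from the series' value table, in which 42.9% (siControl), 43.3% (siControl with adriamycin), 43.1% (siAKR1B10) and 43.4% (siAKR1B10 with adriamycin) of probes were above background. The scanner files deposited under the HCT116 labels hold other measurements: each HCT116 column of the table correlated with the file of the same label at r = 0.871 to 0.889 across probes, against at least 0.9997 for H1299. Genes are not independent replicates, and every correlation given here is across probes or genes.

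**Figure D1:**
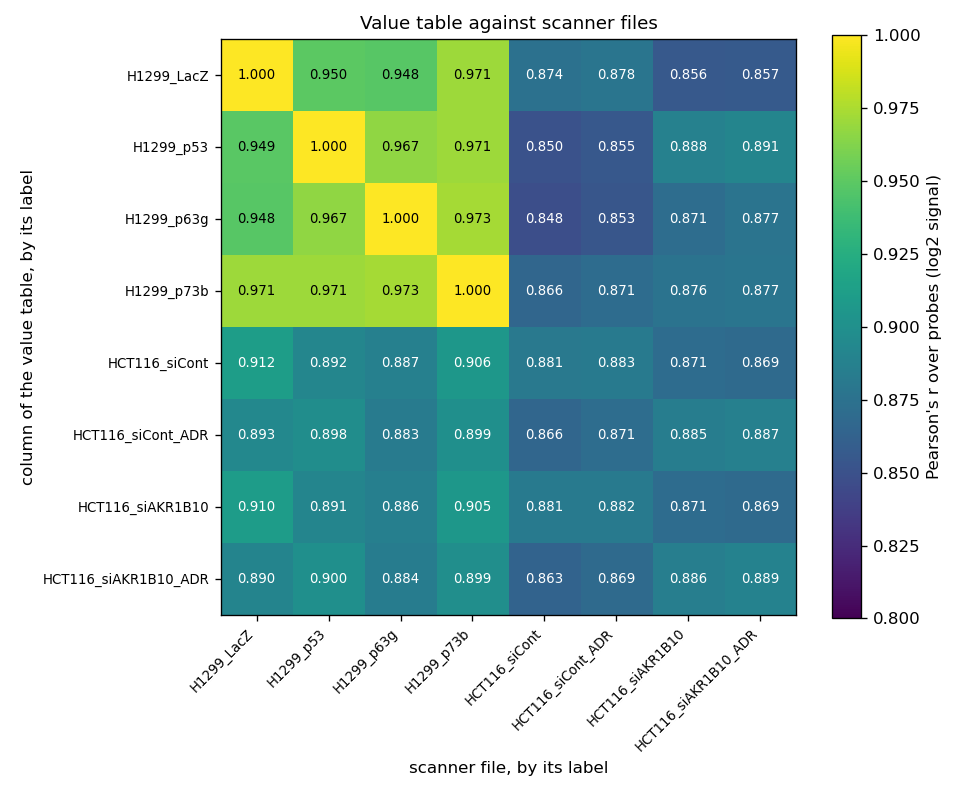
Pearson's r across probes between each column of the value table and each scanned array. The H1299 columns reach at least 0.9997 with the file of the same label, and no HCT116 column exceeds 0.912 with any file.

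TP63 and TP73 stood out on the arrays of their own viruses. TP73 signal was 2617-fold higher on the p73b array than on the LacZ array, and TP63 was at least 15839-fold higher on the p63g array. Where the dimmer array of a pair was not above background, the lowest signal that counted as above background on that array took its place and the fold is a lower bound, written "at least". AKR1B10, the gene silenced in the HCT116 cells, was not above background with LacZ and was at least 304-fold higher with p53. With p63g it was at least 11.6-fold higher and with p73b at least 19.6-fold higher. Compared directly, its level was 26.2-fold lower with p63g than with p53 and 15.5-fold lower with p73b than with p53. The file annotation places its probes on chromosome 7 at 134225799 to 134225858 and at 134225939 to 134225998 (build hg19). The probe of AKR1B15, a near-identical neighbour, followed the same order at 172-fold (p53), 7.81-fold (p63g) and 10.1-fold (p73b), each a lower bound, and the assignment of its signal to AKR1B15 is uncertain. AKR1B1, a further paralog, differed from LacZ by log2 0.17 with p53, −0.42 with p63g and −0.03 with p73b. The file annotation places its probe on chromosome 3 at 74185878 to 74185937, away from the AKR1B10 probes, so the assignment of this signal is uncertain too.

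**Figure D2:**
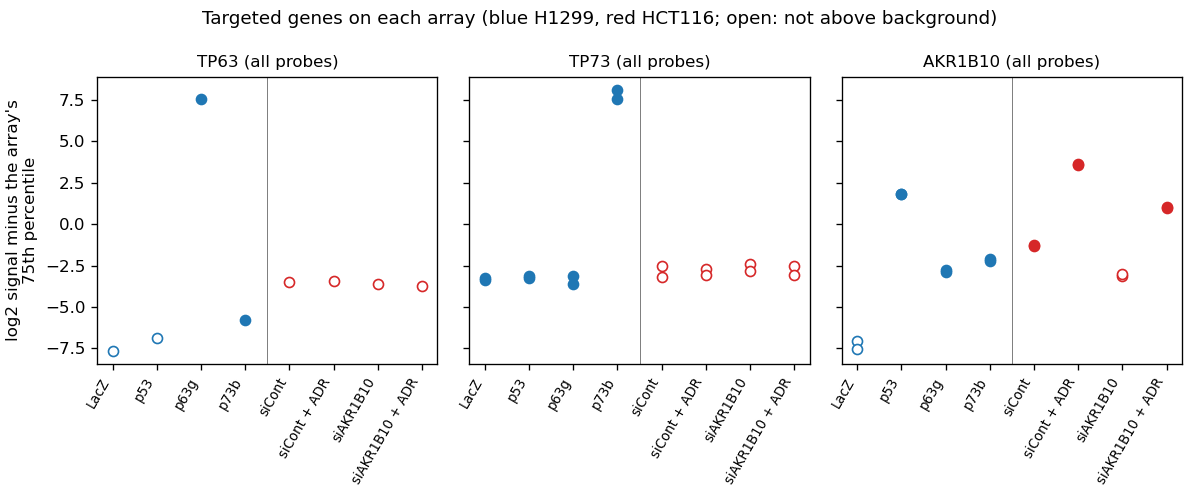
Log2 signal of TP63, TP73 and AKR1B10 minus the array's 75th percentile, 1 point per probe and array, with open points not above background. TP63 is brightest with p63g and TP73 with p73b, and AKR1B10 is brightest with p53 among the H1299 arrays and with adriamycin among the HCT116 columns.

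Infection with p53 against LacZ asked which transcripts differ between cells given the p53 virus and cells given the control virus, whose dose the labels do not give. Genes of the p53 target lists were much higher: MDM2, a ubiquitin ligase, by log2 5.30, the cyclin-kinase inhibitor CDKN1A by 5.72, and SFN, which holds cells before mitosis, by 7.96. The list of p53 cell-cycle and feedback targets had a median log2 difference of 3.38, with 17 of 20 genes at least 2-fold higher, and the p53 apoptosis list had a median of 2.51, led by APAF1 (4.66), TP53I3 (4.70) and FDXR (4.46). Cell-division genes were lower, with a median of −2.29 and 27 of 30 genes at least 2-fold lower for G2/M and −1.38 for G1/S and replication. CENPA, a centromere histone, was lower by log2 −3.58 and the phosphatase CDC25C by −3.41. All of these lists lay outside the range of random lists of like expression.

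Beyond these lists, the largest differences with p53 were in NSG1, an endosomal protein (at least 1619-fold), SULF2, a heparan sulfatase (at least 1362-fold), IHH, a hedgehog ligand (at least 1133-fold), INPP5D, a lipid phosphatase (at least 876-fold), and HES2, a transcriptional repressor (at least 689-fold). KLHL30 (at least 546-fold), LY6D (at least 536-fold), SUSD2 (at least 400.0-fold), the growth factor receptor FGFR3 (378-fold) and FAM43B (at least 367-fold) completed the 10 highest. GLI1, a hedgehog transcription factor, was 17.4-fold lower. The other 9 of the 10 lowest were GPR179 (at least 99.0-fold), BPI, PIWIL3, SLC18A1, PWRN2, TAFA3, LURAP1L, TXNDC8 and GRID1, each read by a probe that was bright on the LacZ array alone. Heat-shock genes were higher (median 1.37), with CRYAB at 4.05 and HSPA1B at 3.76, as were the retinoid list (0.65), the DNA repair list (1.11), the p63-type epithelial list (0.63) and the interferon list (0.47), in which IFIT3 (4.75) and ISG15 (3.78) led and IRF9 (−1.19) went the other way. The stress-response list (−0.84), NF-kB cytokines (−0.96) and lipid and sterol synthesis genes (−0.52) were lower. In total 4328 genes were at least 2-fold higher and 3631 lower of 25275. Another background correction with quantile normalization (normexp) gave 2481 and 2212. Which side held more genes depended on the setting: more were lower after scaling by the median (3885 higher and 4473 lower), which moved the median of all genes by −0.148, after quantile normalization (3926 and 4198) and when both arrays had to be above background (2948 and 3030).

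Among p53 targets with p63g, some were higher by less than with p53 and others by more. CDKN1A was higher by log2 3.53 and MDM2 by 2.94, while PPM1D was higher by 2.53, against 1.40 with p53. The median was 2.23 for the cell-cycle and feedback list (15 of 20 at least 2-fold higher) and 2.54 for the apoptosis list, led by BCL2L11 (4.77), a pro-death BCL2 relative. NDRG1, a stress- and differentiation-linked gene, was higher by 5.64, against 0.35 with p53. Besides TP63 the highest genes were IHH (at least 1411-fold), NSG1 (at least 1149-fold), INHBB, an activin subunit (at least 452-fold), IGFBP3, which binds insulin-like growth factors (427-fold), CCN5, a matrix signalling protein (328-fold), RNF144B, a ubiquitin ligase (325-fold), ADAMTS8 (at least 306-fold), FOXF1 (at least 296-fold) and WNT11 (at least 288-fold). The p63-type epithelial list, of which TP63 itself is a member, had a median of 1.07 (0.97 without TP63), in which the desmosomal gene DSP (3.11) and the laminin chain LAMA3 (3.02) were higher and LAMB3 (−1.15) was lower.

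SLC7A11, the cystine transporter, was 20.4-fold lower with p63g and ARL14 was 22.2-fold lower. BPI, GPR179, PIWIL3, SCML4, PWRN2, TAFA3 and SLC18A1, also among the 10 lowest, again rested on probes bright on the LacZ array alone. G2/M genes had a median of −1.51 (23 of 30 at least 2-fold lower), though CDC20 (1.82) and PTTG1 (1.60) were higher, and G1/S genes a median of −0.83. Heat-shock genes (1.49) and the motile cilia list linked to p73 (1.23, 9 genes measured) were higher and stress-response genes (−0.76) lower, while the interferon list (−0.20) lay within the range of random lists despite IFIT3 at 5.27 and MX1 at 5.14. Counts were 4117 genes higher and 4796 lower of 24633, around a median of all genes of −0.15; with normexp they were 2690 and 2503.

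The p73b array differed from LacZ in fewer genes than the p53 and p63g arrays, and keratins of basal epithelium stood out on it: KRT14 by at least log2 6.02, KRT17 by at least 4.98 and KRT5 by at least 2.95, and the epithelial list had a median of 1.30, with 13 of 21 genes at least 2-fold higher. SFN (7.91), the Notch ligand JAG2 (5.48) and the integrin chain ITGB4 (2.82) belonged to the same group, and the list's median differed little between p73b and p63g (0.012, and 0.089 without TP63, both within the random range). Against p53 the list's median with p73b was 0.247 without TP63, also within that range. SFN (7.96) and JAG2 (5.08) were as markedly higher with p53, whereas ITGB4 was at 0.19 with p53 and 2.65 with p63g. CDKN1A was higher by 2.20 and MDM2 by 3.34, and the p53 cell-cycle and feedback list had a median of 0.98, with 9 of 19 genes at least 2-fold higher. Apoptosis targets had a median of 1.25, including TP53AIP1 at 2.84 or more. Besides TP73 and IHH (at least 1108-fold), the highest genes were STAR, which moves cholesterol into mitochondria (at least 680-fold), the neurotrophin receptor NGFR (516-fold), FGFR3 (403-fold), INPP5D (at least 384-fold), TNNI2 (at least 347-fold), CCN5 (335-fold), LY6D (at least 332-fold) and DUSP13A (at least 308-fold).

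ARL14, a small GTPase, was 81.8-fold lower with p73b. The remaining lowest genes were BPI, GPR179, PIWIL3, PWRN2, TAFA3, TXNDC8, SLC18A1, GRID1 and SPMIP2, read by probes bright on the LacZ array alone. G2/M genes had a median of −1.17 (18 of 30 at least 2-fold lower) and G1/S genes −0.57. The cilia list was higher (0.99), with TEKT2 at 5.79 and DNAI2 at 4.25, while CCNO (−0.47), RFX3 (−0.23) and DNAH5 (−0.04) were lower. TEKT2 and DNAI2 were not particular to p73b: they were at 4.40 and 4.41 with p53 and at 3.56 and 2.99 with p63g. Heat-shock genes (1.01) were higher, and immediate-early genes (−0.50) and stress-response genes (−0.43) were lower. The counts were 2950 higher and 1736 lower of 25393; they were 1555 and 841 with normexp, and 1923 genes were higher when both arrays had to be above background.

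Setting the viruses side by side asked what p53, p63g and p73b share and where they part. IHH, NSG1, SULF2, IGFBP3 (337-fold with p53, 427-fold with p63g, 294-fold with p73b) and RNF144B (307-fold, 325-fold and 135-fold) were the genes highest with all 3. Across 24051 genes measured with every virus, 1383 were at least 2-fold higher with all 3 and 970 lower, while 1013 were higher with p53 alone, 1106 with p63g alone and 340 with p73b alone. Lower with p53 alone were 1111, with p63g alone 2180 and with p73b alone 278. Among the genes furthest apart, p53 exceeded p63g in H19, an imprinted noncoding RNA (241-fold), MLC1 (118-fold) and OR5P3, and p63g exceeded p53 in CCN5 (786-fold), the sialyltransferase ST3GAL1 (at least 105-fold), INHBB (71.7-fold) and the homeobox gene DLX6 (59.2-fold). With p73b, CCN5 (802-fold), KRT14 (at least 62.3-fold), ANXA8L2 (51.3-fold) and the lipid transporter MFSD2A (42.9-fold) lay above p53, and OR5P3, SEPTIN4 (at least 98.3-fold) and TRIM67 lay below it. Between p73b and p63g, TNNI2 (at least 161-fold), KRT14 (at least 58.2-fold), MYOM3 and WFDC5 were higher with p73b and OR52M1, LRRC3B, ADCYAP1 and LBH (42.6-fold) were higher with p63g.

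Relative to p53, cell-cycle and feedback targets were lower with p63g (median −1.01) and with p73b (−1.82), and G2/M genes were higher (0.93 and 1.35). TIGAR, a regulator of glycolysis, was higher by 3.05 with p53 and by 0.27 with p63g, and lower by −0.72 with p73b. Differences of at least 2-fold numbered 6516 between p63g and p53, 5649 between p73b and p53 and 6150 between p73b and p63g. Which side held more genes depended on the scaling: 42.7% of the genes that differed between p63g and p53 were higher with p63g, against 53.8% after scaling by the median and 56.0% with normexp, and for p73b against p63g the share was 56.4%, against 42.8% with normexp. The log2 differences from LacZ correlated at r = 0.718 for p53 and p63g, 0.720 for p53 and p73b and 0.728 for p63g and p73b. All 3 pairs share the LacZ array. Simulated arrays of equal noise with no difference between groups gave r of 0.499 to 0.502, a value that the sharing fixes in advance. Their covariance was 0.012 from spot noise and 0.024 with wider noise, against 1.23, 0.954 and 0.982 observed. It follows from the noise put in, and the wider noise was taken from the siAKR1B10 differences in HCT116. The spread between LacZ cultures was not measured. Genes at least 2-fold higher in both numbered 2287 for p53 and p63g (550 if independent), 1835 for p53 and p73b (387) and 1839 for p63g and p73b (374); lower in both were 2324 (719), 1166 (257) and 1262 (344). With 1 LacZ array the control could not be split, and part of the excess may come from it.

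**Figure D3:**
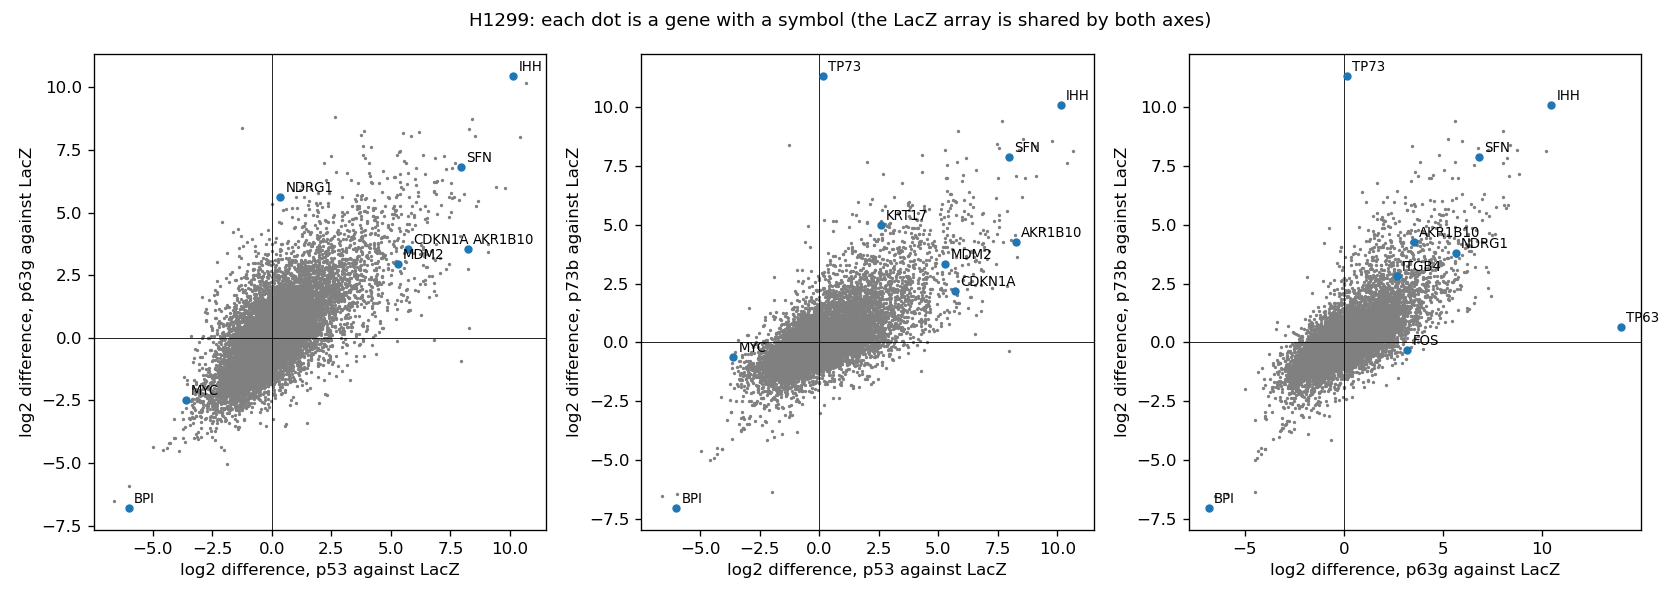
Log2 differences from LacZ of each pair of viruses (x and y axes), 1 point per gene with a symbol, with bounds where an array was not above background. IHH and SFN lie at the upper right of every panel, and over all genes measured in both r was 0.718, 0.720 and 0.728.

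Adriamycin with each siRNA asked what DNA damage does in HCT116 cells and, in this series, to AKR1B10. AKR1B10 was 28.6-fold higher with adriamycin under siControl and at least 8.52-fold higher under siAKR1B10. A p53 response was present with siControl and siAKR1B10 alike: CDKN1A was higher by log2 2.54 and 2.53, MDM2 by 2.80 and 2.78, TP53I3 by 4.72 and 4.95 and the death receptor FAS by 2.58 and 2.58. Medians of the p53 cell-cycle and feedback list were 1.78 (16 of 20 at least 2-fold higher) and 1.77 (17 of 20), and those of the apoptosis list 1.11 and 1.496. Mitotic genes were far lower, with G2/M medians of −3.74 and −3.53 and 29 of 30 genes at least 2-fold lower with each siRNA, PTTG1 being the exception at −0.51 and 0.19. The survivin gene BIRC5 was 44.7-fold and 42.4-fold lower, CCNB2 42.9-fold and 43.6-fold, KIF2C 36.2-fold and 39.6-fold, CENPF 31.3-fold and 31.9-fold, and UBE2C 24.4-fold and 26.8-fold, beside HJURP, HMMR, SPC25, PBK and NDC80. G1/S and replication genes had medians of −2.15 and −2.16.

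Hair-type keratin genes and a noncoding RNA headed the genes higher with adriamycin: KRT34 by at least 48.1-fold and at least 52.9-fold, KRTAP3-1 by 44.3-fold and 68.1-fold, and H19 by 30.1-fold and at least 117-fold. The cysteine-pathway enzyme CBS (23.3-fold and 31.1-fold), XDH, GAST, FXYD3 (15.4-fold and 23.1-fold), TSPAN10 and GRIN2C followed. Interferon-induced genes were higher (medians 1.33 and 1.38, with 15 of 25 and 16 of 27 at least 2-fold higher), among them IFI27 (3.08 and 3.62) and IFIT3 (2.70 and 3.39). Epithelial (0.80 and 0.87), heat-shock (0.67 and 0.48) and DNA repair genes (0.44 and 0.68) were higher, with LAMA3 at 2.81 and 2.88. Stress-response (−0.91 and −0.81), hypoxia and glycolysis (−0.59 and −0.64), lipid and sterol synthesis (−0.34 and −0.38) and motile cilia genes (−0.94 and −0.98, 5 and 7 genes measured) were lower, and SLC7A11 was lower by −2.92 and −2.50. Retinoid genes had medians of 0.68 and 0.35, the latter within the random range, and NF-kB cytokines had medians of 0.32, within that range, and 0.57. Genes at least 2-fold higher and lower numbered 1029 and 1160 of 16014 with siControl, and 1201 and 1263 of 16166 with siAKR1B10. Scaling by the median gave 1101 and 1096 with siControl and 1242 and 1229 with siAKR1B10, so neither side held more genes under both scalings. With the scanner files under the HCT116 labels the division genes were not lower: G2/M medians were 0.64 and 0.19 and G1/S medians 0.38 and 0.058.

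The adriamycin differences under the 2 siRNAs correlated at r = 0.940. At least 2-fold higher with both were 845 genes (76.6 if independent) and lower with both 936 (88.7), with 0 in opposite directions. An additive limma fit of adriamycin and siRNA over the 4 columns, with 1 residual degree of freedom, called 8563 of 16700 genes for adriamycin, of which 4314 rose and 4249 fell. AKR1B10 had a fitted adriamycin difference of log2 4.42. The fit took measured values without bounds, also where a gene was below background, as AKR1B10 was with siAKR1B10 without adriamycin. Its error comes from departures from additivity and does not measure the spread between cultures. In that fit 19 of 20 p53 cell-cycle and feedback genes and 26 of 27 interferon genes rose, and 29 of 30 G2/M and 28 of 30 G1/S genes fell. Some of these calls rest on values below background. The interferon gene MX2, for example, had a fitted rise of 0.973, but with bounds it differed by 0.013 (siControl) and 0.108 (siAKR1B10).

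**Figure D4:**
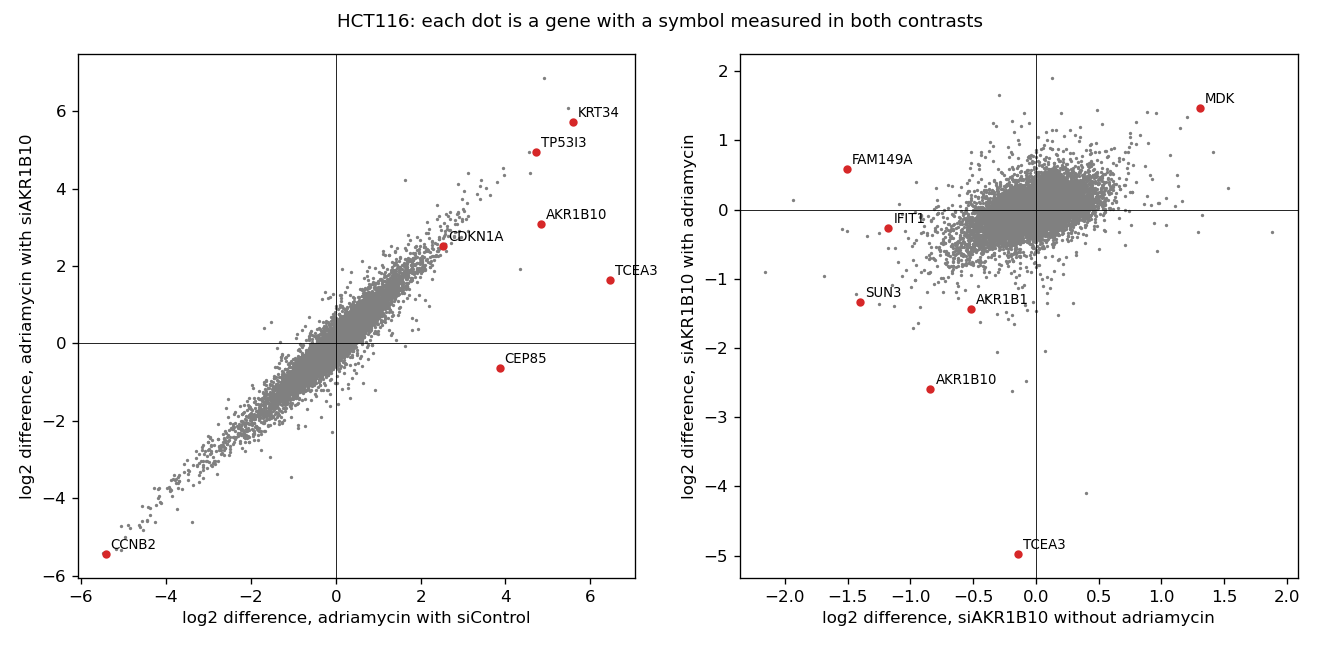
Log2 differences in HCT116 of adriamycin under siAKR1B10 against siControl, and of siAKR1B10 with against without adriamycin, 1 point per gene with a symbol. Over all genes measured in both, r was 0.940 for adriamycin and 0.443 for siAKR1B10, and TCEA3 and CEP85 lie off the trend for adriamycin.

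Comparing siAKR1B10 with siControl asked which transcripts differ when AKR1B10 is silenced. The labels name no other siRNA against AKR1B10, so effects of its loss cannot be told apart from other effects of this siRNA. AKR1B10 itself was at least 1.79-fold lower without adriamycin, where its silenced level was not above background, and 6.01-fold lower with adriamycin. The value table was chosen over the scanner files because AKR1B10 was lower with siAKR1B10 in it. These 2 values are therefore no independent check of the silencing. The interferon list was lower, by a median of −0.44 without adriamycin and −0.10 with it. Without adriamycin IFIT1 (−1.18), IFI44 (−0.91) and IFIT3 (−0.84) were the lowest of the list, and with adriamycin OAS1 (−0.37), RIGI (−0.31) and ISG20 (−0.29). With the scanner files under the HCT116 labels, in which AKR1B10 itself was higher with siAKR1B10, the interferon medians were 0.59 and 0.49. Genes higher in both states included the growth factor MDK (2.47-fold without and 2.77-fold with adriamycin), the vesicle adaptor FYCO1 (2.31-fold and 2.53-fold), the galectin LGALS7 (2.21-fold and 2.26-fold) and the laminin chain LAMC1 (1.94-fold and 2.62-fold), then STRADB, HYAL1, POPDC1, TMCO1, PLAAT3 and IPPK. Lower in both were SUN3 (2.64-fold and 2.53-fold), PPIF, a mitochondrial cyclophilin (2.38-fold and 2.58-fold), the mitochondrial import gene GRPEL2 (2.69-fold and 2.33-fold), RC3H2 (2.19-fold and 2.63-fold), the membrane linker EZR (1.98-fold and 3.26-fold), the matrix proteins CCN1 (3.23-fold and 1.95-fold) and THBS1 (1.95-fold and 2.02-fold), SHISA5, GOLGA7 and AAGAB. AKR1B1 was also lower, by −0.52 and −1.43.

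Small shifts went with these genes. The p53 cell-cycle and feedback list was higher by 0.13 without and 0.20 with adriamycin. Stress-response genes were lower without adriamycin (−0.22) and within the random range with it (0.05). NRF2-type redox genes, which include reductases related to AKR1B10, had medians of −0.12 without and 0.12 with adriamycin, and the epithelial list was higher with adriamycin (0.22). G2/M genes were lower without adriamycin (−0.11), and with adriamycin G1/S genes were higher (0.11) and hypoxia and glycolysis genes lower (−0.11). Retinoid genes (−0.11 and 0.01) and lipid synthesis genes (0.03 and 0.05) lay within the random range. The counts were 63 genes higher and 67 lower of 15614 without adriamycin, and 44 higher and 102 lower of 15749 with it. They depended on the filter: when both arrays had to be above background they were 19 and 26 without adriamycin, and 34 and 57 with it. In simulated HCT116 columns 105 to 250 unchanged genes passed the same size limit, depending on the spread assumed. That simulation was of the adriamycin comparison over 16700 genes, without bounds, and its spread counts any interaction as noise. Without bounds the observed siAKR1B10 counts were 123 higher and 128 lower without adriamycin, and 69 and 200 with it. How many of these genes noise alone would bring past the limit is therefore not settled. The differences correlated at r = 0.443, with 3 genes at least 2-fold higher in both (0.055 if independent) and 6 lower (0.12). The additive limma fit called 0 genes for siAKR1B10, with 2451 at an unadjusted p under 0.05 where chance gives 835 and simulated columns with no siRNA effect gave 817 or 1020, a smallest adjusted p of 0.271, and 691 calls when all 4 columns had to be above background. AKR1B10 had a fitted difference of −2.17, with its measured value below background included, and missed the adjusted threshold as well (adjusted p 0.271).

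Whether silencing changes the response to adriamycin was read from the difference between the adriamycin differences under the 2 siRNAs, which was not tested. TCEA3, a transcription elongation factor, was 88.3-fold higher with adriamycin under siControl and 3.09-fold under siAKR1B10, a log2 difference of −4.84. CEP85, a centrosomal gene (−4.49), the SUMO-activating enzyme SAE1 (−2.40), the sterol enzyme LSS (−2.13) and ATXN7L3B (−1.75) followed, and LSS rested on 1 of its 2 probes. TCEA3 and CEP85 were each far brighter in the siControl column with adriamycin than in the other HCT116 columns. Their values rest on that column, which has no replicate. FAM149A (2.09), SLC49A3 (1.78), the protease CTSH (1.59), its inhibitor family member CSTA (1.52) and the gap-junction gene GJB2 (1.497) lay on the other side. The interferon (0.38), stress-response (0.29), redox (0.21), p53 cell-cycle and feedback (0.15) and epithelial (0.15) lists had higher differences than random lists, and heat-shock genes too (0.15). The interferon, stress-response and redox lists were already lower with siAKR1B10 without adriamycin, and that single column enters each of these values. With adriamycin the interferon list was also lower under siAKR1B10, so its positive value does not mean a higher level after the drug. In all, 40 genes were at least 2-fold higher and 48 lower of 13839.

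**Figure D5:**
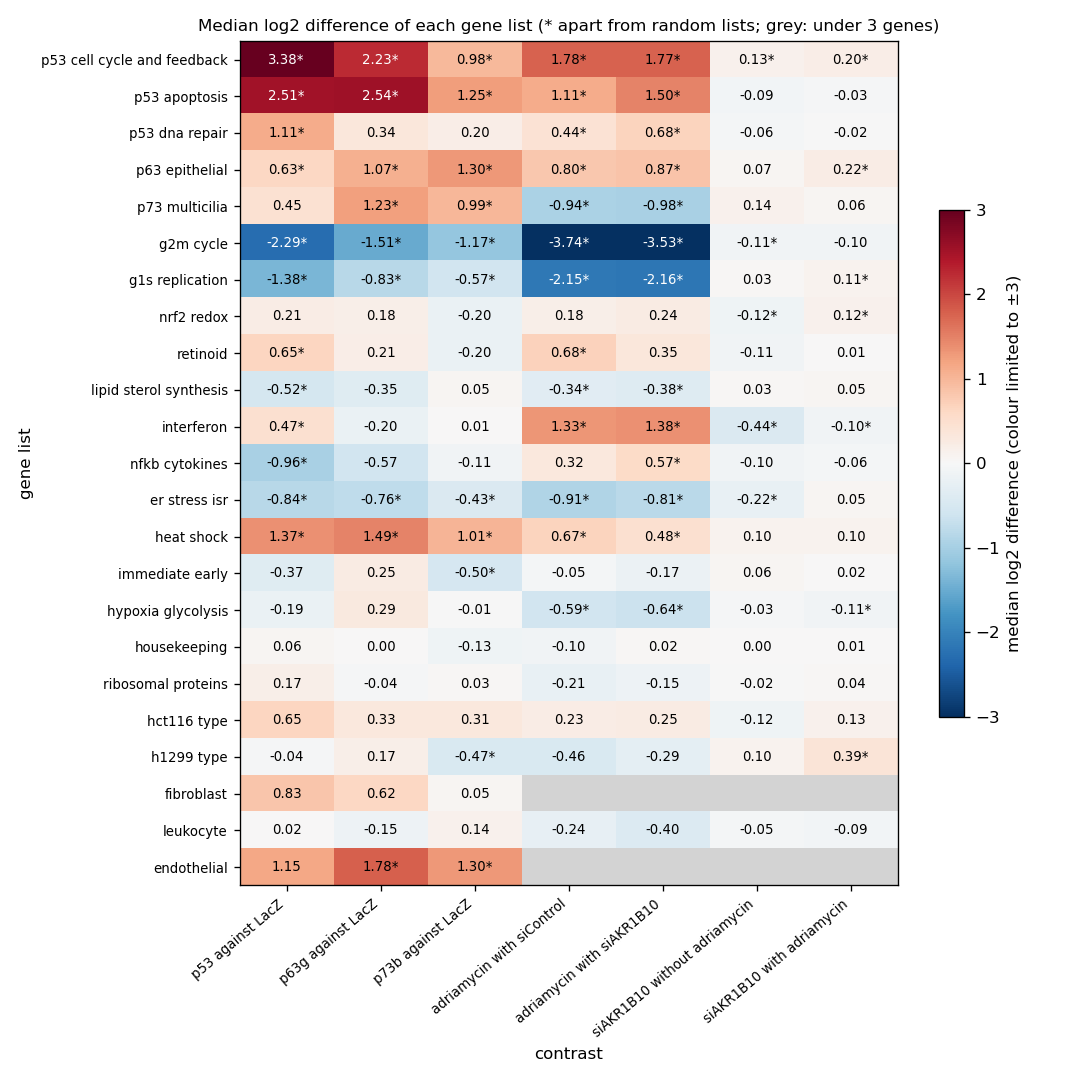
Median log2 difference of each gene list (rows) in each comparison (columns), coloured from blue (lower) to red (higher), with an asterisk where the list lies outside the range of random lists of like expression. p53 targets are higher and cell-division genes lower with each virus and with adriamycin.

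Comparing the lines asked whether adriamycin in HCT116 resembles the p53 virus in H1299. CDKN1A, MDM2, SESN1, TP53INP1, FAS, TP53I3 and FDXR were each at least 2-fold higher with p53, with p63g, with p73b and with adriamycin under either siRNA. Differences with adriamycin under siControl correlated at r = 0.376 with those of p53, 0.239 with p63g and 0.251 with p73b. Shared with adriamycin were 529 genes higher with p53 (149 if independent), 408 with p63g (157) and 280 with p73b (97.3), and 520 (179), 454 (214) and 256 (70.6) lower. With all 3 viruses and with adriamycin under either siRNA, 209 genes were higher (45.5 if independent) and 169 lower (33.5).

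Genes that mark other cell types gave no common direction. The leukocyte list lay within the random range in every comparison measured (medians 0.02 with p53, −0.15 with p63g and 0.14 with p73b), as did the fibroblast list in H1299 (0.83, 0.62 and 0.05, 4 genes) and genes typical of HCT116 (0.65, 0.33 and 0.31). The endothelial list had medians of 1.15 with p53 (3 genes, within the random range), 1.78 with p63g and 1.30 with p73b (4 genes each, outside it), but its genes did not move together: VWF was at 4.44, 1.75 and 3.002, and CDH5 at 0.16, −0.81 and −0.40. The median for p73b was −0.047 when probes below background were kept. Genes typical of H1299 had a median of −0.47 with p73b, outside the random range, with ZEB1 at −1.37 and ZEB2 at −1.35 but SNAI2 at 3.67. For siAKR1B10 with adriamycin their median was 0.39, from 3 genes of which 2 were higher. Housekeeping genes (0.06, 0.00 and −0.13 with the viruses, −0.10 and 0.02 with adriamycin) and ribosomal protein genes (0.17, −0.04 and 0.03, then −0.21 and −0.15) lay within the random range in these comparisons.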

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

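All tests in this part were chosen after the result was seen, as were the size limits that select the genes. The differences between states listed here were not tested.

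Some named genes were at least 2-fold apart in one state and moved by at least 0.5 on the log2 scale the other way in the other. CEP85 differed with adriamycin by log2 3.86 under siControl and −0.63 under siAKR1B10, FAM149A by −1.53 and 0.55, and LSS by 0.92 and −1.21. With siAKR1B10, FAM149A differed by −1.503 without adriamycin and 0.58 with it. The redox list lay outside the random range on opposite sides, with medians of −0.12 without and 0.12 with adriamycin. CEP85 and FAM149A have 1 probe each among those used, and each value rests on single arrays.

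The scanner files under the HCT116 labels, which the comparisons do not use, hold strong signal of genes not above background in the value table's HCT116 columns. AFP had a scaled log2 signal of 8.94 or more on all 4 scanned arrays and ALB 7.04 or more. AKR1B10 was higher there with siAKR1B10 than with siControl, at −1.78 against −2.86 without adriamycin and −0.80 against −2.24 with it.

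The mismatch between these files and the table was weighed. Misordered probes would leave r near 0, and the lowest r of a column with the file of its label was 0.871, while exchanged columns would leave a match with another file, and the highest r with any of the 8 files was 0.912, against 0.9997 or more in H1299. Another normalization of the same arrays would keep ranks, and the highest Spearman's rho over above-background probes was 0.799, while the lowest in H1299 over all probes was 0.9975. The scanned arrays may hold RNA of cells that express liver genes, as files of other samples under these labels would: of 20 liver markers, listed after the mismatch was seen, 20 were above background on all 4 scanned arrays, against 1 in all 4 table columns and 4 on all 4 H1299 arrays. The groups of the design give no biological explanation, and none was tested.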

How the results depend on the processing

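The alternatives that subtract the background level in HCT116, leave out probes bright on the LacZ array alone, or leave TP63 out of the epithelial list were chosen after the data were seen; using the scanner files in place of the value table for HCT116 exchanges the planned source and its alternative. Of 384 values of counts, correlations and overlaps under the alternatives, 317 stayed within the limits (1.5 times for a count, 0.1 for a correlation) and 67 moved. Quantile normalization alone, scaling by the median and the median of a gene's probes moved none. Removal of probes bright on the LacZ array alone moved none either, but it takes out too few genes to reach the limit for a count. Genes lower with p73b, for example, went from 1736 to 1696. Of 1503 values of named genes, 1424 kept their side of 2-fold and, past it, their direction, 33 fell under it, 10 passed it, 2 passed it the other way and 34 reversed. Of 2019 list medians 1905 were the same, 50 came inside the random range, 34 left it, 16 left it with the other sign and 14 reversed. The scanner files under the HCT116 labels hold 34 of the reversed gene values and 13 of the reversed list medians, and with them 15 of 83 gene values and 53 of 103 list medians were the same. Named genes and lists were not recomputed without the probes bright on the LacZ array alone. The cause was not tested for any change below unless one is given.

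Normexp with quantile normalization, whose offset shrinks differences of dim genes by construction, lowered the virus counts: 2481 genes higher and 2212 lower with p53, 2690 and 2503 with p63g, and 1555 and 841 with p73b. It left 3205 genes apart between p63g and p53, 3070 between p73b and p53 and 2885 between p73b and p63g. Higher and lower in both were 1387 and 1366 genes for p53 and p63g, 951 and 606 for p53 and p73b, and 1056 and 618 for p63g and p73b.

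With the value table for H1299, in which background remains, 2831 genes were higher with p53, 3041 lower with p63g, and 1783 higher and 1116 lower with p73b. Genes apart numbered 3856 (p63g and p53), 3653 (p73b and p53) and 3483 (p73b and p63g). Higher in both were 1123 for p53 and p73b and 1213 for p63g and p73b, with 828 lower in both for the latter.

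The filter on both arrays tests fewer genes. It left 1923 genes higher with p73b, 19 higher and 26 lower for siAKR1B10 without adriamycin and 57 lower with it, while the additive fit called 691 genes for siAKR1B10 in place of 0. In that fit 13839 genes entered in place of 16700, and the prior had 9.795 degrees of freedom in place of 3.20. What brought the added calls was not tested.

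With no filter, dim probes enter with their noise. For siAKR1B10, 183 genes were higher and 215 lower without adriamycin, and 87 and 283 with it, 14 lower in both, at r = 0.218. The difference of adriamycin differences gave 869 genes, r between the adriamycin differences was 0.784, and r of p53 with adriamycin was 0.272. The endothelial median with p73b reversed to −0.047. Measured values in place of bounds gave 123 higher and 128 lower for siAKR1B10 without adriamycin, 69 and 200 with it, and 10 lower in both.

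Subtracting the background level in HCT116 widens differences of dim genes by construction. For siAKR1B10 it gave 100 higher and 127 lower without adriamycin, 96 and 179 with it, and 6 higher and 16 lower in both; the difference of adriamycin differences gave 140 genes.

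The scanner files under the HCT116 labels hold other measurements, and with them 2081 genes were higher with adriamycin under siControl and 687 lower under siAKR1B10, at r = 0.511, with 403 higher and 160 lower in both. For siAKR1B10 they gave 3501 higher and 3257 lower without adriamycin, 3652 and 3730 with it, 2537 and 2314 in both, at r = 0.9001. The difference of adriamycin differences gave 898 genes, and the additive limma fit called 0 genes for adriamycin (3048 at an unadjusted p under 0.05) and 5313 for siAKR1B10. Of 44 list medians outside the random range in HCT116, 20 were on the same side.

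These files also reversed directions. With adriamycin, under siControl and siAKR1B10, medians were 0.64 and 0.19 for G2/M, 0.38 and 0.058 for G1/S and 0.22 and 0.15 for motile cilia genes. With siAKR1B10 the interferon list had 0.59 without and 0.49 with adriamycin, and with adriamycin G1/S genes had −2.46 and redox genes −0.17. For the difference of adriamycin differences the p53 cell-cycle and feedback list had −0.31, interferon genes −0.056 and heat-shock genes −0.42. Among genes with adriamycin, under siControl and siAKR1B10, CCNB2 had 0.38 and 0.16, BIRC5 0.59 and 0.2998, KIF2C 1.07 and 0.57, HMMR 0.62 and 0.45, NDC80 0.4999 and 0.33, UBE2C 0.63 and 0.080, and CBS −0.83 and −0.30. Under siControl alone HJURP (0.7002), CENPF (0.39), SPC25 (0.3019), XDH (−0.64) and FXYD3 (−0.92) reversed, and under siAKR1B10 alone TSPAN10 (−0.12). For siAKR1B10, without and with adriamycin, MDK had −0.2032 and −0.11, SUN3 0.5038 and 0.48, and PPIF 0.77 and 0.16. CCN1 (2.88) reversed without adriamycin alone, and HYAL1 (−3.71), TMCO1 (−0.14) and GOLGA7 (0.029) with it alone. For the difference of adriamycin differences, FAM149A had −0.069, TCEA3 0.51, SAE1 0.055 and ATXN7L3B 0.25.

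Signal over background limits what can be seen. In HCT116 42.9% to 43.4% of probes were above background, so lower counts there do not show that fewer genes differed than in H1299. Normexp for HCT116 and a slide term gave no value.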

Other observations

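All tests in this part were chosen after the result was seen.

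A set of 45 probes was at least 8-fold brighter on the LacZ array than on each other H1299 array, and it holds most of the genes lowest against LacZ with the viruses, such as GPR179, BPI and PIWIL3. For the explanation by higher transcript levels in LacZ cells, another probe of the gene followed for 2 of 10 genes (CXCL1 and CXCL2), against 19 of 46 for probes bright on the p53 array alone, with overlapping 95% intervals (exact), so this may hold for some genes only. A defect at single spots would leave the median signal of the spot low, and 60% of the probes were at least 4-fold brighter in it (95% interval 44.3% to 74.3%), against 77.0% for the p53 array, which stays open. Binding of the vector's lacZ transcript also stays open: of the 45 probes, 5 were above background in any HCT116 column, and sequences were not compared. With 1 LacZ array these cannot be told apart.

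AKR1B1, whose probe the file annotation places on chromosome 3, was lower with siAKR1B10. Array scaling does not account for it, since the housekeeping median with adriamycin was 0.0053. An siRNA acting on AKR1B1 by 1 factor in both states does not either: the difference with adriamycin minus that without was −0.917, outside the 95% range of −0.494 to 0.516 among 3819 genes of like signal. Binding of AKR1B10 transcript to the AKR1B1 probe stays open. Fitted on the columns with adriamycin it predicts −0.066 without the drug, where the observed difference was −0.518. The gap of −0.452 lies inside the range of −0.534 to 0.475 among genes of like signal. The observed difference lies inside that range too, so the comparison could not have excluded this binding and does not speak for it. An siRNA effect of different strength in each state and a response of AKR1B1 to the loss of AKR1B10 were not tested, and the siRNA sequence is not given in the labels.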
